A study of Papio hamadryas with 4 samples.

How the data were processed

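Total RNA was extracted from kidney biopsies with Trizol and cleaned on RNeasy columns, labelled with the Illumina TotalPrep kit and detected with Cy3, per the labels. The deposited sample files hold linear signal intensity for 48702 probes, and per the submitters' processing notes the authors used BeadStudio, with no version given. Background correction, normalization and pooling by the authors are not given in the sources used here. The files hold no detection p-value, bead count or error. The arrays' medians differ by more than 5%, so no scaling to a common level is visible in them. A second value table deposited with the series, called the series matrix here, has means that are equal within each phenotype (215 for both NSLC arrays, 192 for both HSLC arrays). Its values rank probes like the sample files (Spearman rho of 0.999 to 1.00), but 49.6% to 49.7% of neighbouring probes are out of order, so it is not a rescaling of them.

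The gene lists, the comparisons, the size rule, the scale rule and the alternatives were chosen before the data were examined, except where the alternatives are said to be added. The scale rule took the sample files, left out 1 probe listed at 0, applied the normexp background correction with an offset of 50, quantile-normalized the 4 arrays and took log2 (limma 3.58.1 in R 4.3.3). A probe counted as detected on an array when its intensity was above that array's median. Of the probes, 23687 carried 1 gene symbol in the annotation given and were used, 35 carried several and 24979 none. Each of 18774 genes was represented by its probe with the highest mean signal, and 11909 genes were detected on all 4 arrays. The probes were designed on human genes and no probe sequence was used here, so a sequence difference between baboon and human can lower a probe's signal.

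The 4 groups are NSLC and HSLC on low and on high sodium, with 1 array each. The comparisons were high against low sodium in NSLC and in HSLC, HSLC against NSLC on each diet, and the difference of the diet ratios. Each is a log2 ratio over genes detected on all arrays it uses, with a size rule of 2-fold, which is not a test. A gene detected on 1 of the arrays only was given a bound, with the other array at its median. The number of arrays limits the precision: no spread between replicates or leave-one-out value can be had, and the difference of the diet ratios has no test. An additive limma fit of diet and phenotype over the 4 arrays, with 1 residual degree of freedom and a moderated error, was added after seeing the data and tested each effect at a Benjamini-Hochberg adjusted p of 0.05 over 11909 genes. Gene lists, 37 of pathways and 20 of cell types, were summarised by the median ratio of detected members. That median was ranked among 10000 random lists of equal size, matched in 20 bins of signal, with limits at the 2.5th and 97.5th percentiles, and this percentile treats genes as if they were independent, which members of 1 list are not.

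Genes were named by a fixed rule. In each diet comparison it takes the 12 highest and 12 lowest ratios among genes above the median signal, and in each other comparison the 6 highest and 6 lowest. From each list it takes up to 4 members with the largest absolute ratio, and a fixed set of sodium transport and renin-angiotensin genes where detected. ANXA10, which falls outside the rule, is named because it passed the size rule on both diets and was chosen after its values were seen.

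The pipeline was tested on simulated data made from the NSLC diet comparison with noise of 0.1 on the log2 scale. Changes were planted in 200 genes, in classes of equal size. Only genes detected on both arrays and represented by the planted probe were counted. The shares below therefore overstate the recovery of all planted genes, most of all in the lower classes, where fewer genes were counted. Of 49 genes with a planted log2 change of 2, 100% passed 2-fold, with a median of 1.64. Of 33 genes with a planted change of -2, 87.9% passed, with a median of -1.43. Of 47 genes with a planted change of 1.5, 89.4% passed, with a median of 1.26, and of 40 with a planted change of -1.5, 47.5% passed, with a median of -0.95. Of 11954 genes with no planted change, 0% passed. That noise was too small for such a gene to reach 2-fold, so the 0% gives no rate of false calls. The standard deviation of the real ratios was 0.20 to 0.28. The offset therefore compresses ratios, and lower genes were found less often than higher genes of the same planted size.

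The alternatives fixed in advance were no normalization, median scaling, cyclic loess, the series matrix in place of the sample files, no detection filter, detection on all 4 arrays, only genes above the median signal, the mean over a gene's detected probes, 1.5-fold, and random lists not matched on signal. Added after seeing the data were an offset of 16, the series matrix as deposited, detection above the 75th percentile, leaving out the skeletal muscle list, the additive fit, and setting the HSLC high sodium sample against both low sodium samples. The remaining tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.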

Results

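Kidney biopsy RNA of baboons (Papio hamadryas) was measured on Illumina bead arrays that carry probes for human genes. The labels give 2 phenotypes, normal SLC (NSLC) and high SLC (HSLC), an abbreviation they do not spell out, and the study's title links them to blood pressure. Each phenotype was sampled after 6 weeks on a low sodium diet and after 6 weeks on a high sodium diet, which makes 4 groups with 1 array each. How many animals stand behind an array, and in which order the diets were given, is not given in the sources used here. With no replicates there is no error on any value. The differences below are log2 ratios of 1 array over another, counted by a fixed size rule of 2-fold, except where a fit over all 4 arrays is named.

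The medians of the deposited intensities were 77.7 in NSLC on low sodium, 79.5 in NSLC on high sodium, 72.1 in HSLC on low sodium and 68.2 in HSLC on high sodium. The 99th percentile was 3298 in NSLC on high sodium and 2320, 2360 and 2490 in the other samples, in the order NSLC low, HSLC low and HSLC high sodium. After normalization the arrays correlated at a Pearson r between 0.977 and 0.993 across genes. The closest pair was the 2 low sodium samples, at 0.993. The lowest Pearson r was that of NSLC on low sodium with HSLC on high sodium (0.977), and the lowest Spearman rho that of the 2 NSLC samples (0.955). For genes with 2 bright probes, the difference between the probes' log2 ratios was taken. Its standard deviation, divided by the square root of 2, was 0.16 to 0.24, depending on the comparison. Of genes at 2-fold on the brighter probe, the other also passed in 1 of 4 in the NSLC diet comparison and 3 of 8 in the HSLC one. It passed in 1 of 3 and 2 of 3 between phenotypes on low and high sodium, and in 0 of 1 for the difference of diet ratios. The sign was shared in 7 of 8 in the HSLC diet comparison and in all such genes of the others.

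The effect of sodium intake in the normal phenotype was the subject of the NSLC comparison. On the high sodium diet the kidney sample held more transcript of tubular injury, complement, matrix and smooth muscle genes, and less of several distal tubule genes. SERPINA3, an acute phase protease inhibitor, was 10.8-fold higher (log2 ratio 3.44). HAVCR1, the tubular injury marker KIM-1, was 6.35-fold higher (2.67), and CFB, a complement component of the alternative pathway, was higher by 2.18. KLK1, the tissue kallikrein made in the connecting tubule, was lower at -1.36, and short of 2-fold without normalization (-0.82) and with median scaling (-0.88). SLC12A3, the thiazide-sensitive sodium-chloride cotransporter, was at -1.10, but at -0.59 without normalization, -0.64 with median scaling and -0.96 with the series matrix, short of 2-fold.

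Among the other strongly higher genes of the NSLC diet comparison were DIO2, a deiodinase that activates thyroid hormone (2.76), and ACTG2, a smooth muscle actin (2.44). FBLN1, a matrix glycoprotein, stood at 2.17, and its other detected probes at 1.59 and 1.87. The stress-induced transcription factor ATF3 was at 1.93, the small G protein RASD1 at 1.89, the transcription factor SOX4 at 1.70, the Wnt pathway modulator SFRP2 at 1.60 and the imprinted noncoding RNA H19 at 1.58. CST6, a protease inhibitor, was at 1.82 on its brightest probe but at 0.30 on its other probe. MMP7, a metalloproteinase of injured tubules, was detected on the high sodium array only and was at least 10.5-fold higher there.

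The kidney injury list had a median of 0.56, with 15 of 18 detected members above 0 and 5 at 2-fold or more, among them SPP1 (osteopontin, 1.47) and KRT19 (1.16). The extracellular matrix list had a median of 0.58, with 28 of 30 members above 0. Its leading members were COL1A1 (1.57) and COL1A2 (1.29), the chains of type I collagen, and the proteoglycan DCN (1.28). The complement list stood at 0.53 with 19 of 20 members above 0, including C1R (1.11) and C1S (1.10). Smooth muscle and fibroblast markers had a median of 0.36, with MYH11, the smooth muscle myosin heavy chain, 2.84-fold higher. MHC class II genes, which present antigen, stood at 0.48 with 10 of 10 members above 0, and macrophage markers at 0.31, led by LYZ (lysozyme, 1.20) and CD68 (0.89). Each of these 6 medians in NSLC lay above all 10000 random lists of equal size and brightness.

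Sodium transport genes had ratios of either sign in NSLC. SLC12A1, the cotransporter of the thick ascending limb, was higher at 1.11, whereas the epithelial sodium channel subunits SCNN1B and SCNN1G were at -0.58 and -0.59 and the alpha subunit SCNN1A at 0.22. Without normalization these 3 were at -0.11, -0.14 and 0.78. FXYD4, a sodium pump regulator of the collecting duct, was at 1.67, and AQP2, its vasopressin-regulated water channel, at 0.60. The distal convoluted and connecting tubule list had a median of -0.34 and that of intercalated cells -0.31 (-0.03 without normalization), led by the transporter SLC4A9 (-1.05). SGK1, an aldosterone-induced kinase, was at -0.22 but at 0.30 without normalization and 0.24 with median scaling. Of the renin-angiotensin genes, AGT (angiotensinogen) was at 0.53, ACE at -0.10 and AGTR1 at -0.02 (0.02 without normalization). The mineralocorticoid receptor NR3C2 was at 0.13 and HSD11B1, which regenerates active glucocorticoid, at 0.89. AGTR1 was barely above the detection limit, with deposited intensities of 82.0 on low and 83.1 on high sodium against array medians of 77.7 and 79.5. A ratio near 0 at that level does not show that the transcript was unchanged.

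The lowest ratios in NSLC belonged to EIF1, a translation initiation factor with 1 detected probe (-2.62), and TNNC2, a troponin of fast skeletal muscle (-2.11). USH1G (-1.46), the olfactory receptor pseudogene OR2A20P (-1.45), the olfactory receptor OR2A1 (-1.34, other probe 0.19) and CYP2C8, an arachidonate epoxygenase (-1.33), followed. The cytokine IL16 was at -1.26, the kinase MAP3K14 at -1.19, ELMOD3 at -1.18 and the pentraxin NPTX1 at -1.07. Without normalization all of these but EIF1 and TNNC2 fell short of 2-fold, USH1G at -0.93 and NPTX1 at -0.62 among them, as they did with median scaling except CYP2C8 (-1.05), and NPTX1 also with the series matrix (-0.94). Erythrocyte and platelet transcripts had a median of -0.46, with the fetal globin HBG1 at -0.85. The skeletal muscle list had a median of -0.57 with 0 of 8 members above 0.

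By the size rule 62 genes were higher and 19 lower among 12191 detected in NSLC, and the standard deviation of all ratios was 0.28. The rule finds lower genes less often than higher genes. In simulated data 47.5% of counted genes with a planted log2 change of -1.5 passed it, against 89.4% of those with 1.5. Planted genes that were not detected on both arrays, or not represented by the planted probe, were not counted. Both shares would be smaller among all planted genes. Of 56 gene lists, 14 medians lay above and 12 below the percentile limits set on random lists, against 2.80 expected in all. Scaling mattered here: without normalization 232 genes were higher and 2 lower, with median scaling 199 and 3, and the median of all genes then stood at 0.27 and 0.23. The proximal tubule list, at -0.25 with MIOX at -0.69 and DPYS at -0.63, moved to 0.19 without normalization and 0.13 with median scaling. The organic ion transport list, at -0.29, moved likewise to 0.14 and 0.09, and fatty acid oxidation, at -0.18, to 0.15 and 0.10, all below the median of all genes in those settings. With the series matrix as deposited the 3 lists stood above that median instead, by 0.12, 0.0081 and 0.0043. The distal tubule median was 0.02 without normalization.

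**Figure D1:**
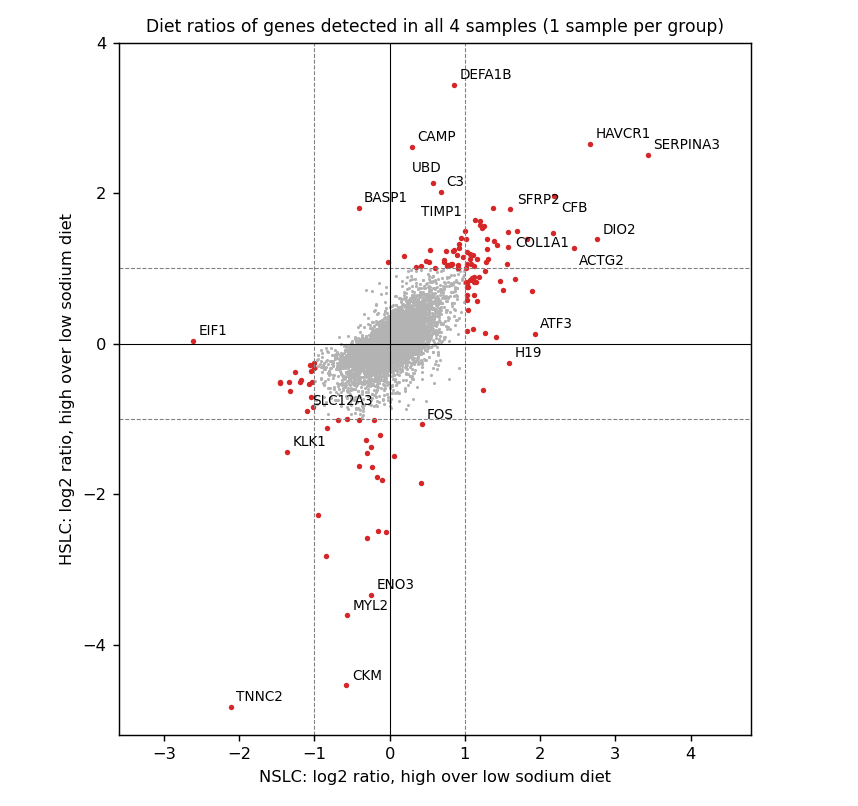
Log2 ratio of high over low sodium diet in NSLC (horizontal axis) against that in HSLC (vertical axis), 1 point for each of 11909 genes detected on all 4 arrays, with dashed lines at 2-fold and genes past 2-fold in either phenotype in red. In the upper right lie 34 genes at 2-fold or more in both phenotypes, SERPINA3 and HAVCR1 among them, and skeletal muscle genes such as TNNC2 and CKM lie far down on the HSLC axis.

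The same diet comparison was made in the high SLC phenotype. Injury, matrix and immune transcripts were again higher on the high sodium diet, proximal tubule transcripts were lower, and skeletal muscle transcripts were far lower. MMP7 was 8.28-fold higher (3.05), HAVCR1 6.31-fold (2.66) and SERPINA3 5.71-fold (2.51). DEFA1B, a neutrophil defensin, was at 3.44 on its brightest probe and 1.73 on the other, and CAMP, the cathelicidin of neutrophil granules, at 2.62. KLK1 was lower at -1.44.

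Complement factors C3 (2.02) and CFB (1.97) were higher in HSLC on high sodium, as were UBD, a cytokine-induced ubiquitin-like protein (2.14), and TIMP1, an inhibitor of metalloproteinases (1.64). SFRP2 was at 1.79 and the adhesion protein FLRT3 at 1.80. BASP1, a membrane-associated signalling protein, was at 1.80 but at 0.53 when the lower of the ratios to both low sodium samples was taken. The kidney injury list stood at 0.62, with 14 of 20 members above 0 and 6 at 2-fold or more. The matrix list stood at 0.47, with 28 of 32 members above 0 and 9 at 2-fold or more, including COL6A3 (1.41) and COL1A2 (1.38). MHC class II genes had a median of 0.66, with HLA-DRA at 1.24 and HLA-DPA1 at 1.09, and macrophage markers 0.62, with LYZ at 1.58 and C1QC at 0.97. The complement list was at 0.28 and the interferon list at 0.25, with the chemokine CXCL10 at 1.23 and GBP2 at 1.17. These 6 medians in HSLC lay above all 10000 random lists.

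Proximal tubule transcripts were lower together in HSLC, with 0 of 23 members above 0 and a median of -0.75. MIOX, which breaks down inositol, was at -1.02, the gluconeogenic enzyme FBP1 at -1.01, HAO2 at -0.89 and the organic anion transporter SLC22A8 at -0.85. The phosphate cotransporter SLC34A1 was at -0.83 in the proximal sodium transport list, whose median was -0.39. Organic ion transporters stood at -0.50 with 2 of 26 above 0, fatty acid oxidation at -0.36 with the peroxisomal enzyme CAT at -0.86, the tricarboxylic acid cycle at -0.22 and oxidative phosphorylation at -0.15. Glycolysis and gluconeogenesis genes had a median of -0.34, but its glycolytic members PFKP and ENO2 were at 0.96 and 0.75. Among sodium transport genes SLC12A3 was at -0.89, SCNN1G at -0.52, SCNN1A at -0.40, SCNN1B at -0.17 and SLC12A1 at 0.19. SGK1 was at -0.36, ACE at -0.28, AGT at -0.04 and AGTR1 at -0.05. AGTR1 was again barely above the detection limit, with deposited intensities of 77.2 on low and 70.5 on high sodium against array medians of 72.1 and 68.2. NR3C2 was at -0.03, but at 0.07 without normalization and 0.10 with median scaling.

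The lowest ratios in HSLC were those of skeletal muscle genes: TNNC2 at -4.83, the myosin light chain MYL1 at -4.65 (other probe -0.65), muscle creatine kinase CKM at -4.54, MYL2 at -3.61, MYL3 at -2.51 and the sarcomere proteins MYOZ1 (-2.83), ACTN3 (-2.58), TCAP (-2.49), TNNC1 (-2.28) and PDLIM3 (-1.86). EEF1A2, an elongation factor of muscle and neurons, was at -3.86, and muscle enolase ENO3 at -3.34 on its brightest probe and -0.12 on its other. The muscle list had a median of -3.61 over 7 detected members. Of 482 and 381 genes detected on 1 array only, 16 found on the low sodium array were at least 2-fold lower on high sodium, among them myoglobin (MB), at least 25.1-fold lower.

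In HSLC 66 genes were higher and 29 lower among 12481 detected, with a standard deviation of 0.27. Of 57 lists, 11 medians lay above and 18 below the percentile limits. Of the 29 lower genes, 20 were 2-fold or more higher in HSLC than in NSLC on the low sodium diet, and 5 were also 2-fold lower against the NSLC low sodium sample. Of the 66 higher genes, 61 were also 2-fold higher against that sample.

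The 2 diet comparisons share no array, and their ratios correlated across 11909 genes at a Pearson r of 0.64 (interval 0.62 to 0.66 from resampling genes) and a Spearman rho of 0.64; genes are not independent replicates. Without the muscle list the Pearson r was 0.65. Genes higher by 2-fold in both phenotypes numbered 34, against 0.333 expected if the calls were unrelated. The count was 61 without normalization, 65 with median scaling, 30 with cyclic loess and 25 with the series matrix. In the main setting these genes were as follows. They held HAVCR1, SERPINA3, SOX4 and KRT19 of injured tubules and COL1A1, COL1A2, DCN and FBLN1 of the matrix. They also held CFB and C1R of complement, LYZ, ACTG2, TIMP1, S100A4 and TGFB2. Genes lower in both were KLK1 and TNNC2, against 0.0415 expected, and TNNC2 alone without normalization and with median scaling. TNNC2, a skeletal muscle gene, was at 8.46 and 11.10 on low sodium in NSLC and HSLC, and at 6.34 and 6.27 on high sodium. For TNNC2, muscle tissue in the low sodium samples cannot be told apart from an effect of the diet. In opposite directions 0 genes passed 2-fold.

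An additive limma fit of diet and phenotype over the 4 arrays, added after the data were examined, tested the part of the diet ratio that both phenotypes share. HAVCR1 rose by 2.66 on average (adjusted p = 8.32e-10, at most 1.22e-05 over the other scalings and the lower offset), SERPINA3 by 2.97 (9.73e-08, at most 0.000211) and CFB by 2.07 (2.3e-08, at most 0.000183). KLK1 fell by 1.40 (6.65e-07, at most 0.000252) in the limma fit, and each of these 4 genes went the same way in both phenotypes. Of 11909 genes, 1039 rose and 839 fell at an adjusted p of 0.05, but the genes that fell numbered 34 without normalization, 73 with median scaling and 416 with cyclic loess. The fit has 1 residual degree of freedom and takes its error from the difference between the diet ratios, pooled over genes, so it holds no spread between animals of a group.

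**Figure D2:**
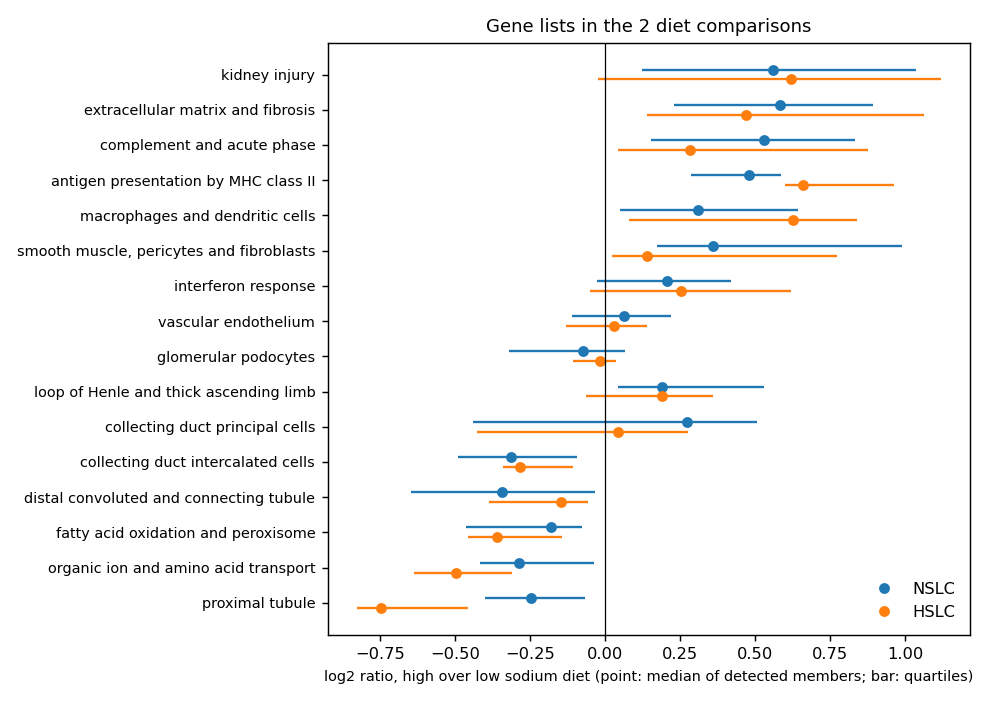
Median log2 ratio of gene lists (horizontal axis) on the high against the low sodium diet, with 1 point per list for NSLC and 1 for HSLC and bars from the lower to the upper quartile of detected members. Kidney injury and matrix medians lie at 0.47 to 0.62 in both and the proximal tubule median at -0.25 in NSLC and -0.75 in HSLC; without normalization the negative NSLC medians of proximal tubule (0.19), organic ion transport (0.14), fatty acid oxidation (0.15), distal tubule (0.02) and podocytes (0.07) turned positive, and so did the HSLC podocyte median with median scaling (0.03) and cyclic loess (0.02).

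On the low sodium diet, HSLC against NSLC asked how the phenotypes differed at low sodium intake. The highest ratios were those of skeletal muscle genes, which stood high in the HSLC sample. Myoglobin (MB) was 17.5-fold higher (4.13), the slow myosin heavy chain MYH7 was at 3.98, CKM at 3.84, MYH2 at 3.84, the fast troponin TNNT3 at 3.63 and MYL1 at 3.48 (other probes 0.25 and 2.81). All 11 detected members of the muscle list were above 0, with a median of 3.48, and 7 more genes were detected in HSLC only and were at least 2-fold higher there. Lower in HSLC were SET, a histone chaperone and phosphatase inhibitor (-1.66), BASP1 (-1.28), DHRS3, which reduces retinal (-1.17), the kinase MAPK13 (-1.07, but -0.96 with median scaling and -0.98 with the series matrix), the membrane skeleton protein ADD3 (-1.01, other probe -0.60) and TNS3, a focal adhesion protein (-1.01).

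Outside muscle, the erythrocyte list had a median of 0.23, with HBG2 at 1.29, and the matrix list 0.14, with SPP1 at 0.85. ISG15, an interferon-induced modifier, was at 1.61. The thick ascending limb list stood at 0.16, the proximal tubule list at -0.15 and oxidative phosphorylation at -0.09. Of the sodium transport genes SCNN1A was at -0.41 and SCNN1G at -0.20, and SLC12A1 at 0.16. SLC12A3 (-0.08), KLK1 (-0.06) and SCNN1B (0.0022) were near 0, and none held its sign: the negative pair turned positive without normalization and with median scaling, and SCNN1B negative with cyclic loess (-0.0115) and the series matrix (-0.0037). In this comparison 35 genes were higher and 6 lower among 12358 detected, with a standard deviation of 0.20, and 28 of the 35 had a level at least 2-fold lower on the HSLC high sodium array, 20 of them detected there and 8 not. With median scaling the lower genes numbered 3.

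On the high sodium diet, HSLC held less transcript of proximal tubule genes than NSLC and more of the neutrophil genes DEFA1B and CAMP and of fetal globin genes. The proximal tubule list had a median of -0.53 with 22 of 23 members below 0, including the urate transporters SLC17A3 (-1.36) and SLC22A12 (-0.99), SLC34A1 (-1.10) and FBP1 (-0.94). SCNN1A was lower at -1.03 (-0.77 with the series matrix), SLC12A1 at -0.77 and AGT at -0.70. ENPEP, the peptidase that cleaves angiotensin II, was at -1.37. DEFA1B was higher at 3.37 (other probe 1.91), CAMP at 2.66, HBG2 at 2.03 and HBG1 at 1.83. The neutrophil list as a whole had a median of 0.06, or -0.16 without normalization.

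Genes of several metabolic lists had low ratios in HSLC on high sodium. HADH (-1.34) and DECR1 (-1.04) of fatty acid oxidation, the glucose-6-phosphate transporter SLC37A4 (-1.33), CTH, which makes cysteine (-1.52), and the secreted glutathione peroxidase GPX3 (-1.02) were lower. The list medians were -0.34 for proximal sodium transport, -0.26 for organic ion transport, -0.18 for the tricarboxylic acid cycle and -0.15 for oxidative phosphorylation. Those of glycolysis and gluconeogenesis (0.02) and of cholesterol and fatty acid synthesis (-0.0075) were near 0, with a sign that depended on the scaling. The NRF2 and oxidative stress list stood at -0.13 with 15 of 16 members below 0, and principal cell markers of the collecting duct at -0.29. Its intercalated cell markers were at 0.0065, or -0.26 without normalization. MT1F, a metallothionein, was at -2.31, TNS3 at -2.24, H19 at -2.01, SET at -1.58 and the immediate early transcription factor FOS at -1.39. EIF1 was at 2.45 and DLK1, an imprinted growth regulator, at 1.52 (other probe 1.23). Erythrocyte genes stood at 0.33 with 10 of 10 members above 0. Macrophage markers stood at 0.20 and T and NK lymphocyte markers at 0.17 with 14 of 14 above 0, medians that were -0.0026 and -0.04 without normalization, when the median of all genes stood at -0.23.

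Of the remaining sodium and renin-angiotensin genes on high sodium, SCNN1B was at 0.41, ACE at -0.20, KLK1 at -0.14 and SCNN1G at -0.12. Without normalization these stood at 0.14, -0.42, -0.46 and -0.42 in the same order, when the median of all genes was -0.23. SLC12A3 was at 0.13 but at -0.17 without normalization and -0.07 with median scaling. In this comparison 12 genes were higher and 44 lower among 12517 detected, with a standard deviation of 0.23. The lower genes numbered 177 without normalization and 118 with median scaling. The phenotype ratios at low and high sodium, which share no array, correlated across 11909 genes at a Pearson r of 0.38. SET, ADD3, TNS3 and DHRS3 were 2-fold lower in HSLC on both diets, and HBG1, HBG2 and ANXA10 higher, against 0.0222 expected for each direction. On low sodium ADD3 and TNS3 were short of 2-fold without normalization (-0.90 and -0.91), with median scaling (-0.88 and -0.88) and with cyclic loess (-0.9990 and -0.9995), and ADD3 also with the series matrix (-0.95). ANXA10 passed on both diets with cyclic loess only among the 4 other scalings. In the additive limma fit SET was lower in HSLC by a mean ratio of -1.62 (adjusted p = 6.88e-07, at most 0.000478 over the other scalings and the lower offset), and 98 genes were higher and 336 lower at an adjusted p of 0.05, counts that were 12 and 123 with cyclic loess.

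**Figure D3:**
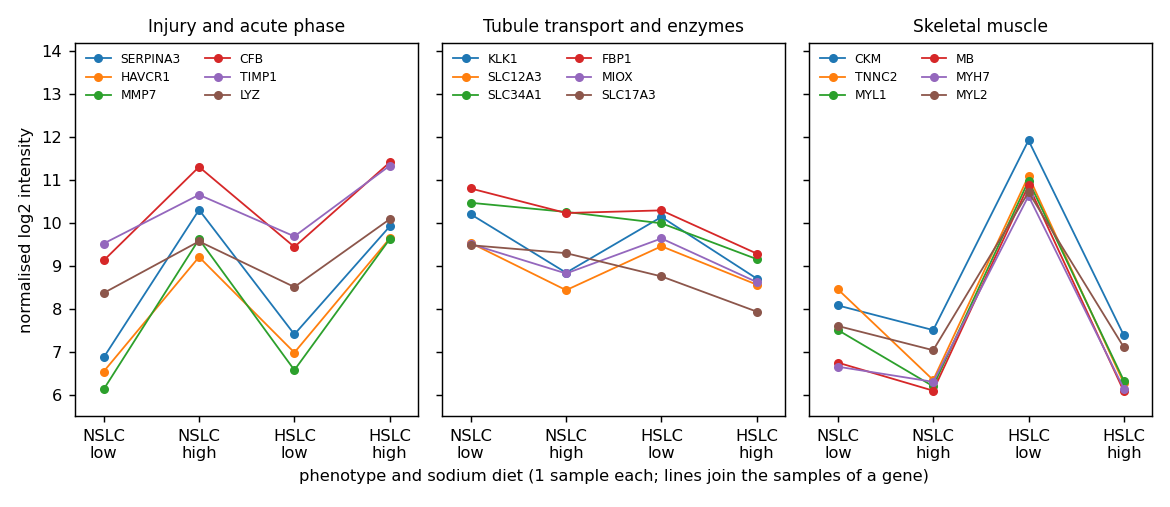
Log2 level (vertical axis, normalized intensity) of named genes in the 4 samples, 1 point per array, with lines joining the points of 1 gene and no error bars since each group has 1 array. CKM stands at 11.93 in the HSLC low sodium sample, and HAVCR1 at 9.21 and 9.64 in the high sodium samples of NSLC and HSLC against 6.54 and 6.98 in the low sodium samples.

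The study's title asks which salt-responsive genes differ by phenotype, which the difference of the diet ratios, HSLC minus NSLC, measures. Skeletal muscle genes led the negative side, and EIF1, the neutrophil genes DEFA1B and CAMP and the complement gene C3 were among the highest on the positive side. CKM was at -3.97, ENO3 at -3.09 (other probe -0.36), MYL2 at -3.05, TNNC2 at -2.71, MYL3 at -2.47 and TCAP at -2.34. On the positive side were EIF1 (2.66), DEFA1B (2.59, other probe 1.63), CAMP (2.32), BASP1 (2.22), UBD (1.56) and C3 (1.34). The CKM level was 11.93 in the HSLC low sodium sample and 7.38 to 8.08 in the others. That of EIF1 was 7.26 in the NSLC high sodium sample and 9.67 to 9.87 in the others. For CKM and EIF1 1 array thus carries the difference. The HSLC low sodium array likewise mainly carries that of ENO3, MYL2, MYL3 and TCAP. ENO3 stood at 11.61 there and at 8.27 to 8.74 in the others. The HSLC high sodium array mainly carries that of DEFA1B (10.61), CAMP (9.94) and C3 (8.87). In the other samples these 3 were at most at 7.24, 7.32 and 7.56. A salt response that differs by phenotype was not tested. The complement list had a median of -0.08 and the neutrophil list of 0.07 (-0.07 without normalization).

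Immediate early genes had a median difference of -0.17, with ATF3 at -1.80, EGR1 at -1.33 and ZFP36 at -1.26. Proximal tubule genes stood at -0.47 with 22 of 23 members below 0, led by SLC22A12 (-0.83) and the endocytic receptor LRP2 (-0.70), and the NRF2 list at -0.22 with SQSTM1 at -0.73 and SOD1 at -0.59. SLC12A1 was at -0.92, SCNN1A at -0.62, AGT at -0.57 and SCNN1B at 0.41. KLK1 was at -0.08. Without normalization SCNN1B was at 0.05, KLK1 at -0.47 and SCNN1A at -1.05, and with the series matrix SCNN1A was at -0.37. SLC12A3 was at 0.20 and SCNN1G at 0.07, and both were negative without normalization and with median scaling. MHC class II genes stood at 0.25 and macrophage markers at 0.25, medians that were -0.06 and -0.12 without normalization, when the median of all genes was -0.23, and 0.0092 and -0.05 with median scaling.

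By the size rule 8 genes had a difference of 2-fold or more above 0 and 34 below it, among 11909, with a standard deviation of 0.23. The latter count was 109 without normalization and 75 with median scaling. It was 29 without the muscle list. That list has 18 genes and leaves out some muscle genes named above, since it held only 6 of the genes lower in the HSLC diet comparison. The remaining differences can thus still include muscle genes. A difference of ratios rests on all 4 arrays, and a change in 1 of them enters it in full.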

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

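All tests of an explanation in this part were chosen after the result was seen.

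In 12 genes above the median signal the diet ratio had opposite signs in NSLC and HSLC, each larger than the spread between probes (0.19 and 0.24), and the difference, HSLC minus NSLC, passed 2-fold. Genes with a smaller ratio on 1 side, such as EIF1 (-2.62 and 0.04), were left out, and with 1 array per group these differences were not tested. For BASP1 and DLK1 the opposite signs depend on the scaling, since their NSLC ratios were 0.05 and 0.24 without normalization and 0.0017 and 0.19 with median scaling. The difference fell short of 2-fold for DLK1 without normalization (0.54), with median scaling (0.61) and with cyclic loess (0.93), for ISG15 with cyclic loess (-0.93) and the series matrix (-0.87), and for DES with cyclic loess (-0.91). Among regulatory and imprinted genes, H19 was at 1.58 in NSLC and -0.26 in HSLC (difference -1.84), and DLK1 at -0.31 and 0.71 (1.02). FOS was at 0.43 and -1.07 (-1.5003) and ZFP36, which promotes decay of cytokine mRNA, at 0.79 and -0.47 (-1.26). The metallothionein MT1F was at 1.25 and -0.62 (-1.87) and MT1G at 0.58 and -0.53 (-1.11). TNS3 was at 0.92 and -0.32 (-1.24), ISG15 at 0.24 and -0.82 (-1.06), and SERPINA6, the corticosteroid-binding globulin, at 0.31 and -0.73 (-1.04). BASP1 was at -0.41 and 1.80 (2.22). The muscle proteins PDLIM3 and DES were at 0.41 and -1.86 (-2.27) and at 0.21 and -0.87 (-1.08).

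Skeletal muscle transcripts stood high in the HSLC low sodium sample, where 17 of 18 list members were detected against 11, 8 and 7 in the NSLC low, NSLC high and HSLC high sodium samples. A phenotype difference present on both diets is argued against, since the same members had a median ratio of 0.0683 (-0.06 to 0.11 over resampled members) between the phenotypes on high sodium and 2.39 on low sodium. Skeletal muscle tissue in the sampled material cannot be told apart from an effect of the diet within HSLC, since the group has no other sample: 82.35% of the detected members, 14 of 17, lay at least 2-fold above the other samples, as both would give, with CKM at 11.93, TNNC2 at 11.10, MYL1 at 10.98 and MB at 10.88. A share of several averaged arrays that held muscle cannot be told apart from another normalization of the series matrix, in which these genes stood 0.2308 higher than in the sample file, relative to genes of equal brightness.

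Injury, matrix and immune transcripts were higher on the high sodium diet in both phenotypes. A lower share of proximal tubule alone would raise the markers of all other cell types alike, yet the macrophage median exceeded the intercalated cell median by 0.6216 (0.26 to 1.02) in the NSLC high sodium sample and by 0.9092 (0.41 to 1.14) in HSLC. This covers only a lower share of proximal tubule alone. Other differences in the mix of cells between the biopsies were not tested and stay open. Diet order or an earlier biopsy cannot be told apart from the diet, since the place in the order of diets is known for 0 samples. A share of several averaged arrays with high levels cannot be told apart from another normalization of the series matrix, since the matrix minus the sample file, relative to genes of equal brightness, was -0.1298 in NSLC and 0.0652 in HSLC on high sodium for the 34 shared genes (log2). An effect of sodium intake stays open, and the additive fit tested it without a spread between animals.

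SET, ADD3, TNS3 and DHRS3 were 2-fold lower in HSLC on both diets, though on low sodium ADD3 and TNS3 were at -0.88 to -0.9995 without normalization, with median scaling and with cyclic loess. A sequence difference from human that all the baboons share would enter both sides of these ratios, so only a difference between the sampled baboons is meant here. For ADD3 such a difference under the probe is argued against, since another detected probe of the gene stood at -0.5991 on low and -0.79 on high sodium. For SET, TNS3 and DHRS3 it cannot be told apart from lower expression, since 0 other probes of these genes were detected on all 4 arrays. A difference between the phenotypes or between the animals sampled stays open, since the additive fit does not part them.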

How the results depend on the processing

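The offset of 16, the series matrix as deposited, detection above the 75th percentile, leaving out the muscle list, the ratio to both low sodium samples and the additive fit were chosen after seeing the data. Of the counts and the correlation, 113 values stayed within 1.5 times (for the correlation, within its interval) and 44 moved; where they moved, the cause was not tested unless given. Without normalization the NSLC diet comparison gave 232 genes higher and 2 lower (main 62 and 19), the phenotype comparison on high sodium 177 lower (main 44), and the difference of diet ratios 109 below 0 (main 34). Median scaling gave 199 and 3 in NSLC, 3 lower between phenotypes on low sodium (main 6), 118 lower on high sodium and 75 below 0 for the difference. With the series matrix in place of the sample files 41 genes were higher in NSLC and the correlation of the diet ratios was 0.599 (main 0.64). As deposited, the matrix gave 12 lower in NSLC and a correlation of 0.571. At 1.5-fold, a looser rule by construction, the counts were 281 higher and 220 lower in NSLC, 285 and 167 in HSLC, 67 and 40 between phenotypes on low sodium, 58 and 270 on high sodium, and 73 above and 146 below 0 for the difference. With no detection filter, which adds genes, 46 were lower in HSLC (main 29), 53 were below 0 for the difference and the correlation was 0.592; for genes above the median signal it was 0.687. The offset of 16, which compresses ratios less, gave 117 higher and 47 lower in NSLC, 119 higher in HSLC (main 66), 79 lower between phenotypes on high sodium and 16 above 0 for the difference (main 8). Against both low sodium samples 5 genes were lower in HSLC, and with detection above the 75th percentile 23 were higher in HSLC on low sodium (main 35). In the additive fit the genes that fell on high sodium (main 839) numbered 34 without normalization, 73 with median scaling and 416 with cyclic loess, and those that rose (main 1039) 1763 with median scaling. Between the phenotypes the higher genes (main 98) numbered 22, 23 and 12 under those 3 scalings and 156 with the offset of 16, and the lower genes (main 336) 165 with median scaling and 123 with cyclic loess. Of named genes, 1293 of 1544 values stayed within the spread between probes and 251 moved. Settings that change only which genes are counted leave a gene's ratio as it is, so 0 moved there by construction. These were detection on all 4 arrays (129 values), no detection filter (137) and genes above the median signal (122). They also were detection above the 75th percentile (111) and leaving out the muscle list (121). Without normalization 66 of 137 moved, and with median scaling 54. Of 994 values of genes at 2-fold, 49 were short of 2-fold and 0 took the opposite sign, though 2 became 0 against both low sodium samples, a setting that puts opposite signs at 0. Of 550 values of genes under 2-fold, 23 turned sign, 22 of them under another scaling. Both totals include the settings that leave ratios as they are. Under the 4 other scalings alone, 31 of 348 values of genes at 2-fold fell short of it. Of 200 values of smaller genes, 22 turned sign there. Of list medians relative to the median of all genes, 1206 of 1272 stayed, 57 moved and 9 reversed. Those with the matrix as deposited were, in NSLC, proximal sodium transport at 0.16, proximal tubule at 0.12, organic ion transport at 0.0081 and fatty acid oxidation at 0.0043, and in HSLC erythrocytes at 0.0147. With no detection filter the osmolyte list in NSLC was at -0.0213. For genes above the median signal principal cells in NSLC were at -0.12 and renin-angiotensin genes in the difference at 0.0028, the latter 0.0027 with detection above the 75th percentile. Of 109 list medians beyond the percentile limits, 106 stayed beyond them with unmatched random lists, 99 with the matrix, 98 with cyclic loess, 89 with median scaling and 85 without normalization. A detection p of 0.05 was not run, since detection p-values were not used here, nor was the planned offset of 50, which is the main setting's own. Dim probes limit what can be seen, since the offset compresses their ratios.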

Other observations

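The tests of an explanation named in the earlier part were chosen after the result was seen, and the values here carry no test. Single neutrophil genes were higher in the HSLC high sodium sample than in the HSLC low sodium sample. DEFA1B and CAMP were 3.44 and 2.62 higher there than on low sodium, MPO (myeloperoxidase) was at 1.09, and MMP9, a metalloproteinase of neutrophils, was higher by at least 1.58, being detected on the high sodium array only. The neutrophil and mast cell list as a whole had a median of 0.07 in that comparison, -0.0090 without normalization. The fetal globins HBG1 and HBG2 passed 2-fold between the phenotypes on both diets, HBG2 at 1.29 and 2.03 in HSLC over NSLC on low and high sodium, while HBB, at 0.32 and 0.75, passed on neither. AHSP, which stabilises alpha globin, was detected in HSLC but not in NSLC on high sodium, and was at least 2.51-fold higher there.

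Single genes of the arachidonate and endothelium lists had positive diet ratios in both phenotypes, short of 2-fold in at least 1 of them, and the list medians were near 0. PTGS1, the constitutive cyclooxygenase, was at 0.97 in NSLC and 0.89 in HSLC, the prostaglandin receptor PTGER3 at 0.87 and 0.72, and VWF, the von Willebrand factor of endothelium, at 1.15 and 0.82. CYP2C8 was at -1.33 and -0.63, and the arachidonate list had a median of -0.08 in NSLC (0.20 without normalization, 0.17 with median scaling) and 0.03 in HSLC (-0.02 without normalization). The vascular endothelium list was at 0.06 and 0.03. Outside these lists S100A4, a calcium-binding protein of migrating cells, passed 2-fold in both at 1.21 and 1.63, and TGFB2 at 1.07 and 1.19. The podocyte list stood near 0, at -0.08 in NSLC (0.07 without normalization and 0.03 with median scaling) and -0.02 in HSLC (0.03 with median scaling and 0.02 with cyclic loess).

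USH1G, OR2A20P, OR2A1, IL16, MAP3K14 and ELMOD3 shared 1 order of levels, with NSLC low sodium highest, then HSLC low sodium, HSLC high sodium and NSLC high sodium. Of probes with no gene symbol in the annotation used here, 8175 were detected in the NSLC diet comparison, with 6 higher and 7 lower by 2-fold, and 8851 in HSLC, with 7 higher and 5 lower. Between the phenotypes on high sodium, 4 of 8606 such probes were higher and 18 lower.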
